A study of Mus musculus with 4 samples.

How the data were processed

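Dendritic cells were grown from C57BL/6 mouse monocytes with GM-CSF, and 4 two-colour expression arrays were deposited. On 2 arrays, cells given lipopolysaccharide (LPS) from E. coli were hybridised against unstimulated control cells. On the other 2 arrays, cells given LPS in the presence of interleukin 4 (IL-4) were hybridised against unstimulated control cells. Per the labels, RNA was extracted on columns, amplified with aminoallyl nucleotides and coupled to Cy3 or Cy5. Replicate 1 of each group had the control in Cy5 and the treated cells in Cy3, and replicate 2 had the dyes exchanged, so the replicate number is also the dye orientation. The labels do not say whether the 2 arrays of a group came from separate cultures or from the same extracts. Control and treated RNA shared each array, and the channels cannot be separated in the values used here.

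The authors deposited 1 processed value per feature and array, which was read as a log2 ratio of the 2 dyes. The values were positive and negative, centred near 0 and rounded to 2 decimals. Their size excluded a log10 ratio, which would exceed what a scanner can record, but a natural logarithm was not excluded, so every fold stated depends on the base being 2. The normalization, the feature extraction and the direction of the ratio are not given in the sources used here. The direction was read from the titles as treated over control and is likely, not certain. The arrays of a group correlated positively over features, so no sign was changed. Intensities were not used here, so the signal over background of a feature is unknown, and the number of arrays limits the precision.

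Of the 45220 features, 33653 (74.4%) had exactly 1 gene symbol, 56 had several and 11511 had none. Features with 1 symbol were averaged per gene and array, which gave 19087 genes, of which 8343 had more than 1 feature. Symbols were brought up to date through Entrez identifiers with the mouse gene table of GRCm38.p6, and 136 features kept the annotated symbol. No read mapping or genome sequence was involved.

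A linear model with 1 coefficient per group was fitted to all 4 arrays with limma 3.58.1 in R 4.3.3 with the data.table package (version 1.17.8), with variances moderated across genes. The model left 2 residual degrees of freedom, and the residual variance was 0 for 11 genes because of the rounding. The 3 comparisons were LPS against control, LPS with IL-4 against control, and the difference of the 2 sets of log2 ratios. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes, and a gene passed at an adjusted p under 0.05. All adjusted p-values of genes and lists are from limma. In this model they measure the spread between arrays, which may be technical. A ratio tested against 0 leaves out the spread of the control cells by themselves.

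Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 30 lists in each comparison. Each result is given with the adjusted p from camera at an estimated correlation, called the estimated-correlation p. For the genes of a list, the number past the test is given over all genes and adjusted over the list alone. The lists were pro-inflammatory cytokines, anti-inflammatory mediators, chemokines, interferon-stimulated genes, NF-kappaB pathway and feedback, DC maturation and costimulation, MHC class II presentation, MHC class I presentation, IL-4 and STAT6 response, Th1-associated DC products, Th2-associated DC products, Notch ligands and receptors, antimicrobial and inflammatory effectors, Toll-like receptors and signalling, monocyte and macrophage genes, dendritic cell genes, lysosome and proteases, glycolysis and hypoxia, cholesterol synthesis, cell cycle, stress response and ribosomal proteins, with markers of T cells, B cells, neutrophils, mast cells and basophils, eosinophils, NK cells, erythroid cells, and fibroblasts and endothelium. Some genes belong to more than 1 list.

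The model, the tests, the lists, the named genes and the first set of alternatives were chosen before the data were examined. Named genes were, per comparison, the 10 with the largest value in each direction among those past the test with the same sign on both arrays, up to 3 members of each list past the test or else the largest member, and 26 key genes whatever their values. Where fewer than 5 genes passed, the 10 largest in each direction at an unadjusted p under 0.01 were named as not passing. Clone and predicted-gene names were skipped. Of the key genes, 25 were measured, and Il12b was not. Other genes named below as list members were chosen after their values were seen.

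Alternatives to the gene tests were median centring, scaling of the arrays to the same spread, quantile normalization, every feature tested by itself, the feature with the largest spread per gene, a filter on genes under 0.5 on all arrays, the replicate number as a block, robust moderation, a variance trend, a minimum of 2-fold, an adjusted p under 0.01, fitting only the arrays compared, and leaving out each array. For lists they were an estimated correlation, fry, centring, the block and leaving out each array. Leaving out an array leaves 1 array in its group and 1 residual degree of freedom, from the pair of the other group, so the lone array is assumed to vary like that pair. A call lost in such a fit says little about stability.

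Further alternatives were added after the data were seen. They combined the block with the filter or with the trend. A filter meant to be independent of the IL-4 difference, called the independent filter, kept genes by their mean over the 4 arrays or their replicate effect divided by 2. Either had to be at least 0.5 in size. The filter is independent only where both groups have the same scale. Rescaling divided the log2 ratios of the arrays with IL-4 by 0.735, the slope of their replicate effect on that of the arrays without IL-4. Scaling to the same spread and quantile normalization were also applied to the lists. Scaling to the same spread means that centred arrays were given the same median absolute value, so their SD was not made equal.

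As a check of pairing, the deviations of the arrays from their group means correlated across genes at r = 0.845 between groups for the same replicate number. This rests on 2 pairs, genes are not independent replicates, and the number is tied to the dye, so the block stayed an alternative. With the block, 1 residual degree of freedom remained. It measures how unlike the 2 groups differ between replicate numbers. A blocked test against control therefore leaves out the disagreement between replicates that both groups share. On simulated data with the observed replicate effect and 200 changed genes, the unblocked fit recovered 0% of genes changed by log2 2 and 15.2% of those changed by log2 3 in LPS against control. For LPS with IL-4 against control it recovered 1.49% and 7.58%, and for the difference 0% at both sizes, without false calls. The blocked fit recovered 64.2% and 83.3% in the difference, and 0.741% of its calls were false. With the independent filter added, it recovered 92.5% and 97.0%, and 2.42% of its calls were false. In the simulated difference, a list of 20 genes raised by log2 1 was called and 0 of 29 unchanged lists were. The simulations gave both groups the same replicate effect and let genes vary independently. In the data the replicate effect with IL-4 had a slope of 0.735 on that without, and genes may be correlated. The simulations therefore give no rate of false calls for these data. Figures were drawn with matplotlib 3.10.9.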

Results

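Gene expression was measured on 4 two-colour arrays of mouse monocyte-derived dendritic cells grown with GM-CSF. LPS, a bacterial cell wall product that activates these cells through Toll-like receptor 4, was compared with unstimulated control cells on 2 arrays. LPS in the presence of IL-4, the cytokine typical of type 2 helper T cell (Th2) responses, was compared with control cells on the other 2. No array held cells given IL-4 alone. Values are log2 ratios, likely treated over control, and are given with the SD between the 2 arrays of a group.

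Each array had values for 45220 features. The SD over features was 0.614 and 0.589 on the LPS arrays, and 0.494 and 0.467 on the arrays with IL-4. A value of exactly 0 was held by 4.65% and 5.49% of features on the LPS arrays, and by 20.7% on each array with IL-4. Over features, the 2 arrays of a group correlated at r = 0.474 for LPS and 0.507 for LPS with IL-4. Arrays of different groups with the same replicate number correlated more closely, at r = 0.810 and 0.797, although features are not independent replicates. The replicate number, which is also the dye orientation, moved 923 of 19087 genes by at least log2 1, and 36 genes had opposite signs of at least that size on the 2 arrays of both groups.

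The first comparison asked what LPS does to these cells. As lists, cytokines, chemokines, interferon-stimulated genes and DC maturation genes were higher after LPS, with 3 of 18, 3 of 20, 5 of 31 and 3 of 20 members past the test over all genes. The lists of lysosomal proteases, MHC class II presentation and cell cycle were lower, with 1 of 18, 0 of 13 and 2 of 25 members past it. These list calls rest on a preset inter-gene correlation, and none of them held at an estimated one (adjusted p 0.192 to 0.464). The test at an estimated correlation has 2 residual degrees of freedom, and few lists could pass it. The largest rise among genes past the test was that of the neutrophil-attracting chemokine Cxcl1, at 6.13 ± 0.68 (SD, n = 2 arrays, adjusted p 0.0413), or 70.0-fold. Il23a, which encodes the IL-23 subunit p19, rose by 4.97 ± 0.28 (SD, n = 2, adjusted p 0.0294), and the anti-inflammatory cytokine Il10 rose by 4.86 ± 0.49 (SD, n = 2, adjusted p 0.0442).

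Other strong rises included the chemokine Ccl3 (4.28 ± 0.28, SD, n = 2), the phospholipase Pla1a (4.26 ± 0.05), Shisa3 (4.20 ± 0.32) and the vasoactive peptide gene Edn1 (4.14 ± 0.03). The transcription factor Lhx2 rose by 4.12 ± 0.23, Il1a by 4.04 ± 0.46 and the MAP kinase phosphatase Dusp2 by 3.93 ± 0.35. Adjusted p in this group lay between 0.0263 for Pla1a and 0.0407 for Lhx2. Interferon-beta (Ifnb1) rose by 2.77 ± 0.04 and the interferon-induced Usp18 by 3.52 ± 0.02 (SD, n = 2). The costimulatory ligand Cd80 rose by 3.10 ± 0.16, the maturation marker Cd83 by 1.57 ± 0.04, and the transcription factors Irf4 and Irf8 by 2.23 ± 0.11 and 1.94 ± 0.19. Among genes that fell were the cholesterol ester hydrolase Nceh1 (−3.61 ± 0.01, SD, n = 2), Lpar6 (−3.49 ± 0.47), the endosomal Rab7b (−3.46 ± 0.23) and Cd300c2 (−3.29 ± 0.28). Others were the ubiquitin ligase Rnf128 (−3.19 ± 0.33), Sash3 (−2.74 ± 0.01) and the DNA-sensing adaptor Sting1 (−2.73 ± 0.02). The mRNA decay factor Zfp36l1 (−2.71 ± 0.30), the ERK phosphatase Dusp6 (−2.40 ± 0.15) and Hacd4 (−2.25 ± 0.12) also fell. The mitotic genes Birc5 and Ccnb2 fell by 2.06 and 2.02. Rab7b missed the threshold with the replicate block (adjusted p 0.0595), as did Zbp1 (1.95, adjusted p 0.0488 without and 0.0536 with the block), Hif1a (1.30, 0.0488 and 0.0609) and Gapdh (0.57, 0.0462 and 0.0503).

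Several classical LPS targets had large values that missed the threshold. Il6 stood at 6.28 ± 1.38 (SD, n = 2, adjusted p 0.0788), Tnf at 3.98 ± 1.32 (0.110), Ptgs2 at 4.82 ± 0.90 (0.0605) and Il1b at 3.89 ± 0.36 (0.0662). The lymph node homing receptor Ccr7 stood at 3.81 ± 0.80 (0.0866), Cd40 at 3.05 ± 1.21 (0.123), Cd86 at 1.82 ± 0.13 (0.0558) and Nos2 at 1.35 ± 0.42 (0.113). For Il12a, a subunit of IL-12, the value was 2.21 ± 0.39 (0.0548). With the replicate number as a block, limma called Il6 (adjusted p 0.0397), Ptgs2 (0.0414), Ccr7 (0.0397), Cd86 (0.0435), Il12a (0.0468), Nos2 (0.0435) and Socs1 (2.66 ± 0.86, 0.0405). It did not call Tnf (0.0536), Il1b (0.0812) or Cd40 (0.123). Ccl22 read 5.15 on replicate 1 and 0.15 on replicate 2, and was called with the block (0.0420). A blocked call against control therefore does not show that the 2 arrays of a group agree. The Notch ligands Jag1 (−0.10 ± 0.02), Jag2 (−0.05 ± 0.06) and Dll4 (0.21 ± 0.10) and the Th2-associated Tnfsf4 (0.06 ± 0.15) did not pass. Neither did Pdcd1lg2 (0.31 ± 0.83), Arg1 (0.15 ± 0.29), Mrc1 (−0.20 ± 0.34), Chil3 (−1.43 ± 0.98), Ccl17 (2.52 ± 0.97) or Il4ra (1.01 ± 1.07). Retnla (−1.25 ± 0.83, adjusted p 0.332) did not pass either, but was called lower with the block (0.0417).

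In limma, 161 genes rose and 181 fell after LPS, of which 100 and 91 moved at least 2-fold. At an unadjusted p under 0.05 there were 3628 genes, where chance gives 954. With the replicate block, 498 genes rose and 638 fell, and 281 of the 342 calls were shared. No gene passed in limma when any of the 4 arrays was left out, with 2338 to 4708 genes at an unadjusted p under 0.05, but those fits take the spread from the 1 group left with a pair and could hardly pass. None passed when the arrays were scaled to the same spread (2009 genes at that p).

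**Figure D1:**
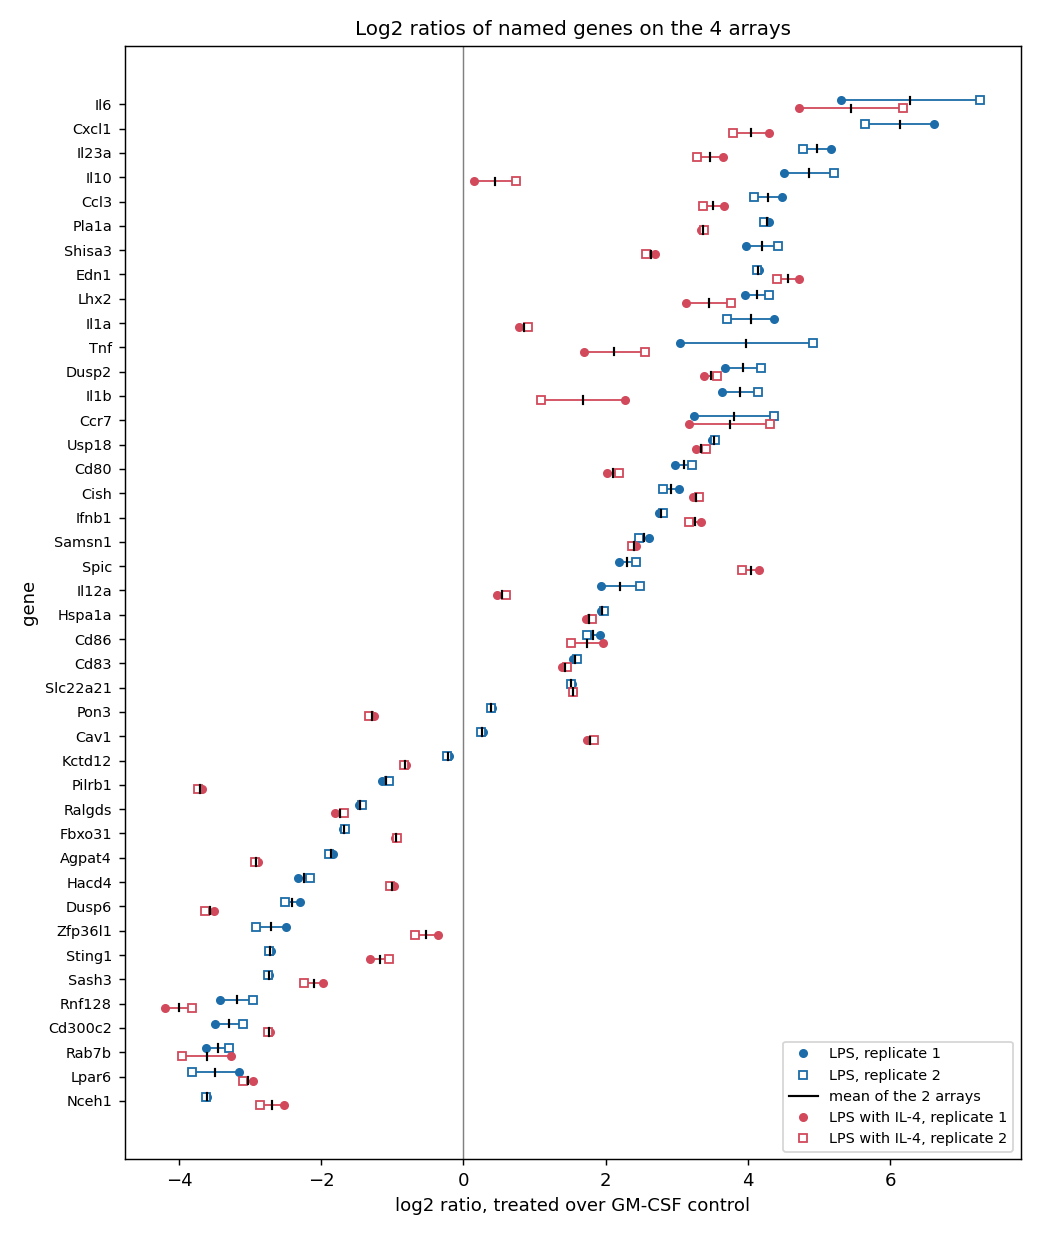
Log2 ratios of named genes on each array (circles for replicate 1, squares for replicate 2) and their group means (black ticks), for LPS and for LPS with IL-4 against unstimulated control. Il6 averages 6.28 with LPS and 5.44 with IL-4 added, while Il10 averages 4.86 and 0.45.

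Of the 30 gene lists, camera called 14 after LPS, and none at an estimated correlation. All 14 kept direction and call when the arrays were scaled to the same spread or quantile normalised. By fry, 11 of them passed, but not MHC class II (adjusted p 0.213), antimicrobial effectors (0.121) or ribosomal proteins (0.128). Cytokines had the median log2 ratio 2.54 over 18 genes (adjusted p 8.33e-14, estimated-correlation p 0.192), with 3 past the test over all genes and 16 higher when adjusted over the list alone. Interferon-stimulated genes were higher on both arrays for 31 of 31 members, with median 1.62 (adjusted p 2.43e-17, estimated-correlation p 0.192), 5 past the test and 25 adjusted over the list alone. Chemokines had median 2.59 (adjusted p 8.65e-08, estimated-correlation p 0.192; 3 passed, 10 adjusted over the list alone), and anti-inflammatory mediators 1.63 (8.29e-08, estimated-correlation p 0.294; 6 and 13). DC maturation genes had median 0.97 (2.75e-08, estimated-correlation p 0.192; 3 and 11), Th1-associated products 1.09 (2.12e-11, estimated-correlation p 0.192; 3 and 12), and NF-kappaB genes 1.72 (2.12e-05, estimated-correlation p 0.192; 1 and 2).

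Glycolysis and hypoxia genes had median 0.61 after LPS (adjusted p 7.97e-05, estimated-correlation p 0.192), and 8 were higher and 1 lower when adjusted over the list alone. Antimicrobial effectors had median 0.70 (adjusted p 0.000331, estimated-correlation p 0.464), with 0 past the test over all genes and 6 higher and 1 lower adjusted over the list alone, but missed the threshold without LPS replicate 2 (0.0752). Stress genes had median 0.59 (0.00614, estimated-correlation p 0.256), with 4 higher and 1 lower adjusted over the list alone, and missed it without LPS replicate 1 (0.223) or 2 (0.0752). Lower as lists were lysosome and proteases (median −0.85, 6.14e-06, estimated-correlation p 0.221), with Ctsd at −0.94 ± 0.11 past the test and 8 genes lower adjusted over the list alone, and MHC class II presentation (−0.80, 0.00082, estimated-correlation p 0.464; 1 lower adjusted over the list alone). Ribosomal proteins (−0.70, 6.38e-05, estimated-correlation p 0.464; 0 adjusted over the list alone) were lower too, as was cell cycle (−0.31, 0.00164, estimated-correlation p 0.221; 2 higher and 5 lower adjusted over the list alone).

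Lists not called after LPS were IL-4 and STAT6 response (median 0.17, adjusted p 0.389; by fry called higher, 0.0494), MHC class I (−0.00, 0.593), Notch (0.00, 0.593), dendritic cell genes (−0.05, 0.893) and cholesterol synthesis (−0.06, 0.942). Th2-associated products (0.15, adjusted p 0.180; by fry 0.0494), Toll-like receptors (0.34, 0.109) and monocyte and macrophage genes (−0.71, 0.130) were not called either, but were with the replicate block (0.0205, 0.0373 and 0.0205). Markers of other cells were not called, with adjusted p of 0.199 for T cells, 0.427 for B cells, 0.469 for neutrophils, 0.208 for mast cells and basophils, 0.667 for eosinophils, 0.469 for NK cells, 0.389 for erythroid cells and 0.232 for fibroblasts and endothelium. The median and the mean differed in sign for MHC class I, dendritic cell genes, cholesterol synthesis, eosinophil and NK cell markers.

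The second comparison asked what LPS does when IL-4 is present. As lists, interferon-stimulated genes, cytokines, chemokines and IL-4 and STAT6 response genes were higher than in control, with 2 of 31, 0 of 18, 0 of 20 and 1 of 30 members past the test over all genes. The lists of lysosomal proteases and of monocyte and macrophage genes were lower, with 0 of 18 and 0 of 19 members past it. None of these list calls held at an estimated correlation (adjusted p 0.160 each), and by fry the monocyte and macrophage list did not pass (0.0808). The rises and falls given next passed without the replicate block, and none of them passed with it (lowest adjusted p 0.0637). Edn1 rose by 4.57 ± 0.22 (SD, n = 2 arrays, adjusted p 0.0472), and the transcription factor Spic, which macrophages of the red pulp need, rose by 4.04 ± 0.16 (SD, n = 2, adjusted p 0.0473). Ifnb1 rose by 3.25 ± 0.12, Usp18 by 3.34 ± 0.10, the STAT-induced inhibitor Cish by 3.27 ± 0.06, Pla1a by 3.36 ± 0.03 and Samsn1 by 2.40 ± 0.04. The caveolar protein gene Cav1 rose by 1.78 ± 0.06, Slc22a21 by 1.54 ± 0.00 and Cd83 by 1.43 ± 0.05. Hspa1a rose by 1.77 ± 0.06, although 1 of its 4 features pointed down. The genes that fell were Pilrb1 (−3.71 ± 0.04, SD, n = 2), Dusp6 (−3.57 ± 0.08), Agpat4 (−2.91 ± 0.03), Ralgds (−1.74 ± 0.08), Pon3 (−1.29 ± 0.05), Fbxo31 (−0.95 ± 0.02) and Kctd12 (−0.82 ± 0.01).

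With IL-4, Il6 stood at 5.44 ± 1.03 (SD, n = 2, adjusted p 0.190), Ccr7 at 3.74 ± 0.81 (0.182), Il23a at 3.46 ± 0.26 (0.0642) and Cd80 at 2.10 ± 0.12 (0.0630). Next came Tnf at 2.12 ± 0.61 (0.461), Il1b at 1.68 ± 0.83 (0.349), Il12a at 0.53 ± 0.09 (0.518) and Il10 at 0.45 ± 0.41 (1.00). None of them passed. Ccl24, an eosinophil-attracting chemokine, stood at 4.75 ± 1.13 (0.154) and Chil3 at 2.06 ± 2.68 (0.974), again without passing.

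In limma, 17 genes rose and 7 fell with IL-4, of which 15 and 5 moved at least 2-fold, and 1932 genes had an unadjusted p under 0.05. With the replicate block limma called 0 genes, with a lowest adjusted p of 0.0637 and 3453 genes at an unadjusted p under 0.05, and no gene passed when any array was left out (951 to 1975 genes at that p), again with the spread from 1 group alone. Of the calls, 14 rises and 5 falls were shared with LPS against control, where independence would give 0.143 and 0.0664. Both comparisons used control cells that may be the same, and 20 simulations with unchanged genes and a shared control gave r = 0.495 between the mean log2 ratios, where the observed r was 0.802. The simulations made no calls, so they say nothing about shared calls. They held the replicate effect, which cancels in the group means, and put as much variance in the shared control as in the treated cells. That choice sets the simulated r. The covariance of the mean log2 ratios was 0.171 observed and 0.00292 on average in the simulations. Across replicate numbers the 2 groups correlated at r = 0.506 and 0.393, where the replicate effect runs opposite ways on the arrays compared and lowers r. Because the control cells may be the same in both comparisons, the observed r and the shared calls cannot be put down to the treatments alone.

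**Figure D2:**
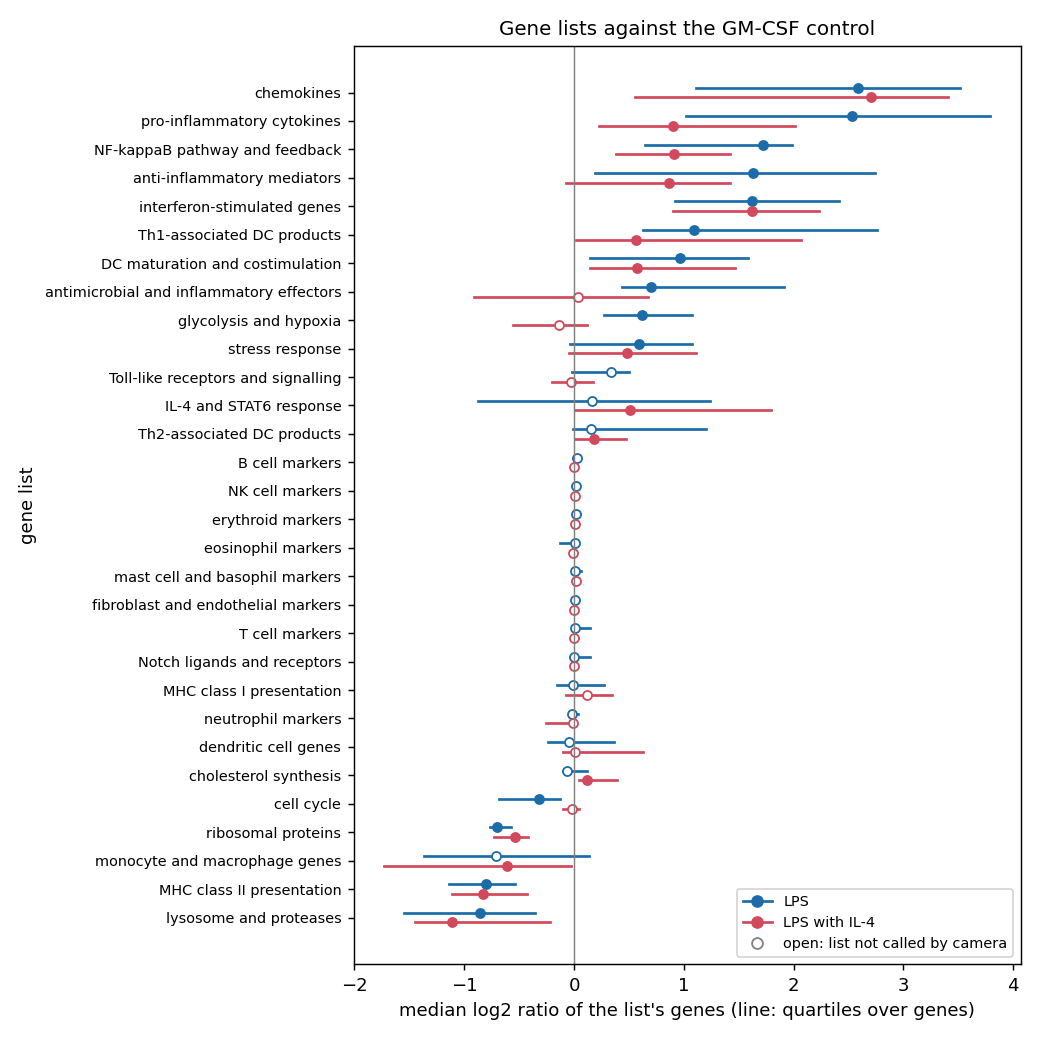
Median log2 ratio of each gene list against unstimulated control, for LPS and for LPS with IL-4, with lines over the middle quartiles of the members and open symbols for lists that camera did not call. Cytokines read 2.54 and 0.91, and interferon-stimulated genes 1.62 and 1.62.

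With IL-4, camera called 15 lists, again none at an estimated correlation. By fry, 10 of them passed, but not MHC class II (adjusted p 0.275), Th2-associated products (0.122), monocyte and macrophage genes (0.0808), stress genes (0.0854) or ribosomal proteins (0.269). Interferon-stimulated genes had median 1.62 (adjusted p 8.7e-27, estimated-correlation p 0.160), with 30 of 31 higher on both arrays, 2 past the test and 21 adjusted over the list alone. Chemokines had median 2.71 (5.7e-11, estimated-correlation p 0.160; 7 higher and 1 lower adjusted over the list alone), cytokines 0.91 (1.25e-11, estimated-correlation p 0.160; 6 higher) and anti-inflammatory mediators 0.87 (4.71e-07, estimated-correlation p 0.287; 10 higher and 2 lower). NF-kappaB genes had median 0.92 (3.07e-06, estimated-correlation p 0.160; 2 higher), DC maturation 0.57 (3.22e-11, estimated-correlation p 0.160; 7 higher) and Th1-associated products 0.56 (5.91e-10, estimated-correlation p 0.160; 8 higher). IL-4 and STAT6 response genes, not called by camera with LPS alone, had median 0.51 (1.37e-07, estimated-correlation p 0.160; 6 higher) and cholesterol synthesis 0.12 (0.000135, estimated-correlation p 0.160; 0). Stress genes had median 0.48 (0.0019, estimated-correlation p 0.192; 3 higher and 1 lower) and Th2-associated products 0.18 (0.00832, estimated-correlation p 0.287; 2 higher and 1 lower), the last not called without replicate 1 of LPS with IL-4 (0.0648).

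Lower with IL-4 than in control were lysosome and proteases (median −1.11, adjusted p 1.94e-08, estimated-correlation p 0.160; 5 lower adjusted over the list alone) and monocyte and macrophage genes (−0.61, 2.44e-05, estimated-correlation p 0.160; 8 lower). So were MHC class II (−0.83, 2.74e-05, estimated-correlation p 0.399; 3 lower) and ribosomal proteins (−0.54, 4.83e-07, estimated-correlation p 0.394; 0). Antimicrobial effectors (median 0.04, adjusted p 0.588), glycolysis (−0.14, 0.164), cell cycle (−0.01, 0.784), Toll-like receptors (0.998), MHC class I (0.539), Notch (0.865) and dendritic cell genes (0.206) were not called. Markers of T cells (0.482), B cells (0.998), mast cells (0.439), eosinophils (0.588), NK cells (0.830), erythroid cells (0.644) and fibroblasts and endothelium (0.588) were not called. Those of neutrophils (0.0630) were not either, but passed without LPS replicate 1 or 2 (0.0332) and without replicate 2 of LPS with IL-4 (0.0466). The sign of the test differed from that of the median or the mean for Notch, Toll-like receptors, cell cycle and markers of T, B and NK cells.

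The third comparison asked what IL-4 changes in cells given LPS, the subject of the series. Without an array of IL-4 alone, an effect of IL-4 by itself cannot be told from a change in the response to LPS. A positive difference need not be a rise above control. Cell cycle genes, for example, had the median log2 ratio −0.315 with LPS and −0.015 with IL-4 against control. By the list test at a preset correlation, glycolysis and hypoxia genes, antimicrobial effectors, and monocyte and macrophage genes were lower with IL-4, and the lists of IL-4 and STAT6 response, cholesterol synthesis and cell cycle were higher. None of these calls held at an estimated correlation (adjusted p 0.338 to 0.417), by fry only glycolysis and cell cycle passed, and no member passed over all genes. The IL-4 and STAT6, cholesterol and monocyte and macrophage lists also lost the call without LPS replicate 1 (0.0524, 0.181 and 0.158). Cytokine and Th1-associated lists were lower as deposited, again not at an estimated correlation (0.365 and 0.338), while interferon-stimulated genes were not called. How far these hold also depends on the scale of the arrays with IL-4, whose ratios had a smaller spread over all genes (slope 0.794 on those without IL-4) though not in every gene or list, and the dependence is given with each list.

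No single gene passed in this comparison in limma, with a lowest adjusted p of 0.231 and 1369 genes at an unadjusted p under 0.05, and the replicate block gave 0 as well (0.230 and 2581). A blocked fit on 2866 genes kept by the independent filter, both chosen after seeing the data, called 234 genes higher and 244 lower, and 247 of these had an unadjusted p under 0.05 without the block. After rescaling of the arrays with IL-4 it called 158 higher and 185 lower of 3351 genes, and 233 genes were called with the same sign both ways. The adjusted p-values given with single genes in the next paragraphs are from this filtered and blocked limma fit, first as deposited and then rescaled. The blocked fit left 1 residual degree of freedom. As deposited, the variance borrowed across genes counted for 10.8 degrees of freedom with the filter and 1.01 without it. These p-values therefore rest mostly on the borrowed variance, not on the spread of each gene. As deposited, the filter is also not independent of the difference. The smaller ratios with IL-4 shift the difference of genes with large means, so calls there can reflect the scale.

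Among named genes the lowest difference was that of Il10, at −4.41 ± 0.08 (SD of the 2 replicate-matched differences, n = 2; adjusted p 8.71e-07 and 0.00527), with all 10 of its features lower. Il1a differed by −3.19 ± 0.56 (SD, n = 2; 1.66e-05, rescaled −2.89), the granulocyte growth factor Csf3 by −2.71 ± 0.37 (3.03e-05, rescaled −2.63) and the LPS co-receptor Cd14 by −2.62 ± 0.16 (2.87e-05, rescaled −2.77). The siderophore-binding Lcn2 differed by −2.85 ± 0.80 (5.85e-05, rescaled −2.53) and Il12a by −1.67 ± 0.30 (0.000662, rescaled −1.48, 0.0190). Further low values were those of Gstt4 (−3.28 ± 0.18), the histamine-forming enzyme Hdc (−3.06 ± 0.02), the collagenase Mmp13 (−2.78 ± 0.64) and the prostaglandin synthase Ptges (−2.62 ± 0.13). They also included Pilrb1 (−2.61 ± 0.11), the inhibitory Fc receptor Fcgr2b (−2.50 ± 0.09, 12 features), Saa3 (−2.38 ± 0.81) and Ier3 (−2.12 ± 0.16). Scaling to the same spread turned Saa3 to 0.23 and left the signs of Il10, Il1a, Csf3, Cd14, Lcn2, Il12a and Hdc. It moved Il10 to −2.08, Il1a to −0.91, Csf3 to −1.35, Cd14 to −2.00, Lcn2 to −0.65, Il12a to −0.38, Hdc to −0.21, Gstt4 to −1.60, Mmp13 to −0.82, Ptges to −1.69 and Ier3 to −1.05, without a call. The same scaling moved Pilrb1 to −5.68 and Fcgr2b to −5.15, also without a call.

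Some genes of the IL-4 and STAT6 list were higher with IL-4. The filtered and blocked fit called 9 higher and 3 lower of the 18 it tested, with Slc7a2 (−1.95) among the lower ones, and the filter did not keep Arg1 (−0.20) or Mrc1 (0.14). Ccl24 differed by 3.54 ± 0.65 (SD, n = 2; adjusted p 1.05e-05, rescaled 5.25), Chil3 by 3.48 ± 1.70 (0.000235, rescaled 4.22) and Retnla by 2.41 ± 0.09 (4.51e-05, rescaled 2.83). The transcription factor Egr2 differed by 3.20 ± 0.57 (1.66e-05, rescaled 3.36) and the ribonuclease Rnase2a, listed as Ear11, by 2.38 ± 0.09 (4.55e-05, rescaled 3.32). The cell fusion gene Ocstamp differed by 2.73 ± 0.03 (2.25e-05, rescaled 3.52) and Zfp36l1 by 2.18 ± 0.07. The fatty acid receptor Cd36, kept by the filter after rescaling only, differed by 3.27 ± 0.35 (rescaled 3.83, 0.00570). Slc25a13 differed by 2.05 ± 0.11, Spic by 1.73 ± 0.34, Rbp4 by 1.73 ± 0.40 and the lysosomal lipase Lipa by 1.71 ± 0.56. Gstm5, kept by the filter after rescaling only, differed by 1.98 ± 0.53 (rescaled 2.50, 0.0113). The filter did not keep Endod1 (2.12 ± 0.27), so it was not tested there. Birc5, which fell with LPS alone, differed by 1.68 ± 0.30 (0.000645, rescaled 1.54). Zfp36l1 fell with LPS alone too. These values are differences from LPS alone and need not be rises above control. The genes given here as higher kept their sign when the arrays were scaled to the same spread or quantile normalised, but not their size. Scaled to the same spread, Zfp36l1 read 0.70, Lipa 0.69 and Birc5 0.56, while Spic read 5.55, Ccl24 7.41, Rnase2a 4.29 and Ocstamp 4.06, without a call.

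Other cytokines and surface molecules depended on the scale. Tnf differed by −1.85 ± 0.71 (SD, n = 2; adjusted p 0.000807, rescaled −1.09, 0.0572), Il1b by −2.21 ± 1.19 (0.00101, rescaled −1.61, 0.115) and Il23a by −1.50 ± 0.02 (0.00102, rescaled −0.25, 0.472). Cd80 differed by −0.99 ± 0.04 (0.0114, rescaled −0.23, 0.502), Socs1 by −1.18 ± 0.18 (0.00493, rescaled −0.65, 0.194) and Nos2 by −0.92 ± 0.13 (0.0178, rescaled −0.76, 0.0785). Scaled to the same spread, Tnf (1.28), Il1b (0.59), Il23a (3.02), Cd80 (1.78) and Socs1 (0.97) read higher with IL-4, without a call. That scaling multiplied the arrays with IL-4 by 1.71 and the LPS arrays by 0.569 and 0.603. Genes raised in both groups therefore tend to read higher with IL-4 under it. It was used in the unfiltered fit, which called no gene in this comparison. Il6 turned from −0.84 ± 0.35 (0.0331) to 1.13 (0.0297) after rescaling, and Ccr7 from −0.07 ± 0.01 (0.872) to 1.29 (0.0271). Scaled to the same spread, Il6 read 5.61, Ccr7 4.15, Ifnb1 3.94 and Ccl22 4.30, none with a call. On rescaling, Ifnb1 went from 0.48 ± 0.16 (0.179) to 1.66 (0.0139). Il4ra, kept by the filter after rescaling only, differed by −1.60 ± 0.76 (rescaled −1.81, 0.0217). Ccl22 differed by 0.75 ± 0.23 (0.0477), and missed the threshold after rescaling (1.98, 0.0810). As deposited, values were small or spread widely for Cd86 (−0.09 ± 0.19), Cd40 (−0.64 ± 1.39), Ccl17 (0.61 ± 1.59), Arg1 (−0.20 ± 0.28) and Mrc1 (0.14 ± 0.31), but scaled to the same spread Cd86 read 1.90, Cd40 2.32 and Ccl17 3.88, without a call. Small values as deposited were also those of Jag1 (−0.01 ± 0.06), Jag2 (0.04 ± 0.05), Dll4 (−0.20 ± 0.06), Tnfsf4 (0.10 ± 0.00) and Pdcd1lg2 (0.13 ± 0.20).

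**Figure D3:**
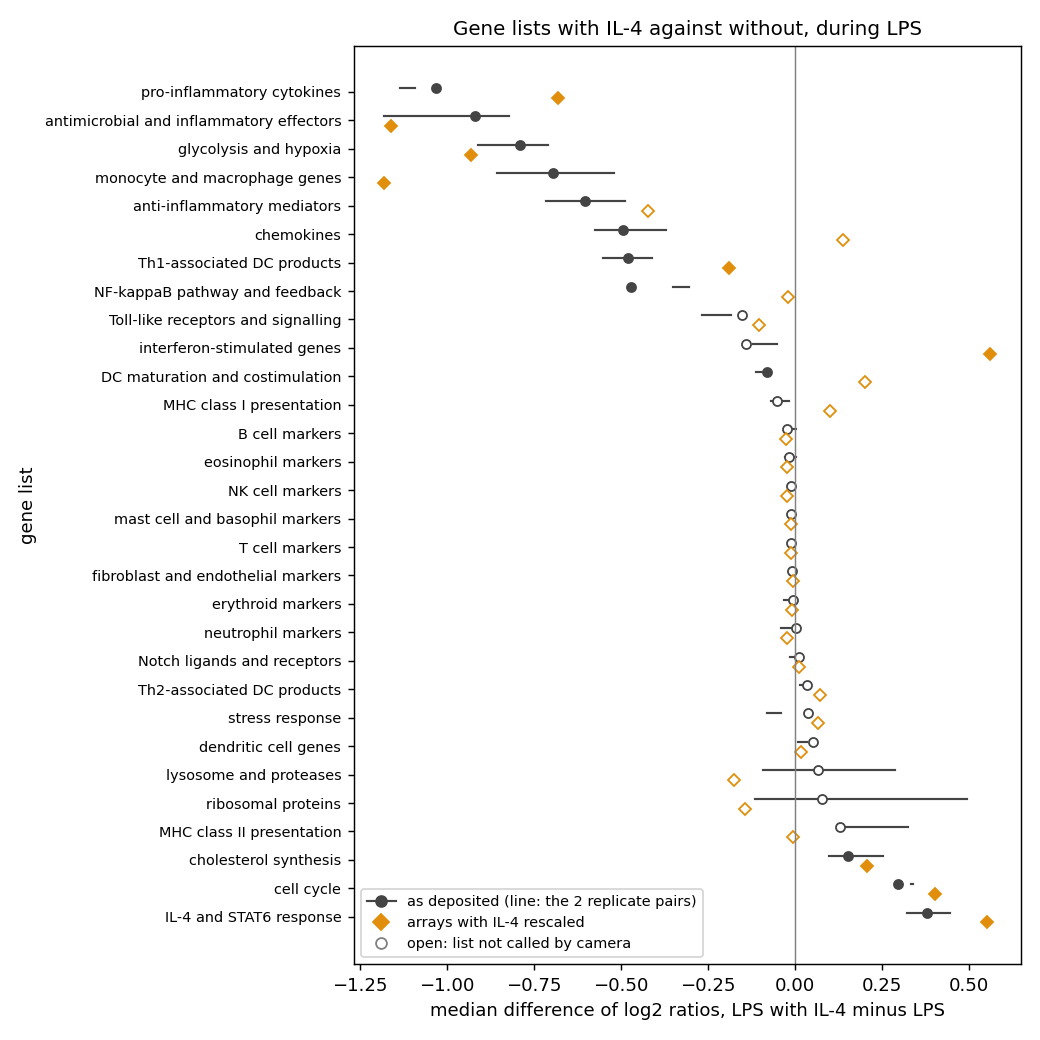
Median difference of log2 ratios per gene list, LPS with IL-4 minus LPS, as deposited and after rescaling, with open symbols for lists that camera did not call and lines joining the medians of the 2 replicate pairs, which need not enclose the point. Glycolysis and hypoxia reads −0.79 and −0.93, and interferon-stimulated genes −0.14 and 0.56.

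Camera called 12 lists in this comparison, none at an estimated correlation. Glycolysis and hypoxia genes had the median difference −0.79 (adjusted p 2.73e-09, estimated-correlation p 0.338), with 15 of 19 lower in both replicate pairs, 0 past the test over all genes and 5 lower adjusted over the list alone. Their members included Bnip3 (−2.14), Slc2a1 (−1.67), Hk2 (−1.52) and Hif1a (−1.31). Cell cycle genes had median 0.30 (1.82e-07, estimated-correlation p 0.338), with 23 of 25 higher in both pairs and 2 adjusted over the list alone. Antimicrobial effectors had median −0.92 (1.09e-06, estimated-correlation p 0.417), with 17 of 19 lower in both pairs and 0 adjusted over the list alone. These 3 lists kept direction and call when any array was left out, with the replicate block, with rescaling (medians −0.93, 0.40 and −1.16), with quantile normalization (−0.82, 0.34 and −0.89) and with scaling to the same spread (−0.66, 0.21 and −0.65). By fry, glycolysis and cell cycle passed (adjusted p 0.0358 each) and the other lists did not.

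IL-4 and STAT6 response genes (median 0.38, adjusted p 0.0032, estimated-correlation p 0.383; 3 higher and 1 lower adjusted over the list alone), cholesterol synthesis (0.15, 0.00288, estimated-correlation p 0.383; 0) and monocyte and macrophage genes (−0.70, 0.0032, estimated-correlation p 0.383; 3 lower) kept their direction and call under the same scalings. They lost the call without LPS replicate 1, with adjusted p of 0.0524, 0.181 and 0.158, and the IL-4 list and the monocyte and macrophage list also without LPS replicate 2 (0.490 and 0.109), in fits with 1 residual degree of freedom. Genes with opposite signs were among them, such as Cd36 against Fcgr1 (−1.82), and Ccl24 against Slc7a2 (−1.95).

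Cytokines had median −1.03 (adjusted p 4.14e-10, estimated-correlation p 0.365), with 15 of 18 lower in both pairs and 1 higher and 11 lower adjusted over the list alone. They stayed lower after rescaling (−0.68, 2.34e-05) and quantile normalization (−0.83, 5.44e-08), but the median turned to 0.31 (0.882) when the arrays were scaled to the same spread. Th1-associated products had median −0.48 (4.09e-06, estimated-correlation p 0.338; 1 higher and 6 lower adjusted over the list alone), −0.19 after rescaling (0.0125) and 0.00 when scaled to the same spread (0.345). Anti-inflammatory mediators had median −0.60 (0.000247, estimated-correlation p 0.460; 1 higher and 5 lower), −0.42 after rescaling (0.408), 0.47 scaled to the same spread (0.00787), and no call without LPS replicate 2 (0.109).

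Chemokines (median −0.50, adjusted p 0.0303, estimated-correlation p 0.418), NF-kappaB genes (−0.47, 0.0315, estimated-correlation p 0.383) and DC maturation genes (−0.08, 0.0176, estimated-correlation p 0.383), each with 0 genes adjusted over the list alone, were called as deposited and lost the call on rescaling. Rescaled medians were 0.14 (0.829), −0.02 (0.823) and 0.20 (0.764), and scaling to the same spread gave 2.32, 0.62 and 0.87. Without LPS replicate 1 the adjusted p was 0.349, 0.349 and 0.418. Chemokines and NF-kappaB genes also missed the threshold without LPS replicate 2 (0.168 and 0.377) and without replicate 1 of LPS with IL-4 (0.174 and 0.0528), and DC maturation without replicate 2 of LPS with IL-4 (0.145) and with the block (0.116). Interferon-stimulated genes were not called as deposited (−0.14, 0.291), but were higher with IL-4 after rescaling (0.56, 0.0154) and when scaled to the same spread (1.68, 6.28e-14).

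Not called in this comparison were Toll-like receptors (median −0.15, adjusted p 0.103), which passed with the block (0.00226) and without replicate 2 of LPS with IL-4 (0.0306). MHC class II (0.13, 0.650), MHC class I (−0.05, 0.650), Th2-associated products (0.04, 0.755), Notch (0.01, 0.460), dendritic cell genes (0.05, 0.749), lysosome and proteases (0.07, 0.749), stress (0.04, 0.314) and ribosomal proteins (0.08, 0.714) were not called either. Scaled to the same spread, MHC class II (−0.68, 0.000178), lysosome (−0.99, 9.5e-06) and ribosomal proteins (−0.50, 5.71e-05) were called lower. Markers of T cells (0.585), B cells (0.569), neutrophils (0.450), mast cells (0.296), eosinophils (0.809), NK cells (0.685), erythroid cells (0.601) and fibroblasts and endothelium (0.302) were not called. Median, mean and test did not share a sign for MHC class I, Th2, Notch, dendritic cell and stress genes and for B cell, neutrophil and eosinophil markers.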

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

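The comparison of cytokines with interferon-stimulated genes was tested after the result was seen, while the tests of the replicate number and of the smaller ratios were chosen before. The rescaling and the list tests after scaling to the same spread were added after the data were seen.

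With IL-4, 12 gene lists differed from LPS alone by a direct test of the difference of log2 ratios (camera, adjusted p). They were cytokines (4.14e-10, median −1.03), glycolysis and hypoxia (2.73e-09, −0.79), cell cycle (1.82e-07, 0.30), antimicrobial effectors (1.09e-06, −0.92) and Th1-associated products (4.09e-06, −0.48). Anti-inflammatory mediators (0.000247, −0.60), cholesterol synthesis (0.00288, 0.15), the IL-4 and STAT6 response (0.0032, 0.38) and monocyte and macrophage genes (0.0032, −0.70) followed. DC maturation (0.0176, −0.08), chemokines (0.0303, −0.50) and NF-kappaB genes (0.0315, −0.47) had the weakest tests. None passed at an estimated inter-gene correlation (lowest adjusted p 0.338).

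Arrays with the same replicate number deviated together, at r = 0.845 over genes. Probes of the same gene resembled each other less in this replicate effect (r = 0.132) than in the LPS effect (r = 0.389), a difference of 0.257 (95% bootstrap interval 0.201 to 0.315, 4333 pairs). That argues against a difference between cultures as the whole cause, since it would move all probes of a gene alike. Gene-specific dye bias of single probes may be part of it, and had the values it needs. A difference between cultures as a part of it stays open, because replicate number and dye go together.

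Log2 ratios were smaller with IL-4, with a slope of 0.794 (0.767 to 0.820) for the treatment effect and 0.735 (0.719 to 0.751) for the replicate effect. The difference of the slopes was −0.0597 (−0.0894 to −0.0286), so the replicate effect, which the treatment does not define, shrank at least as much, which is consistent with compression of all ratios on these arrays. Values of dim probes set near 0 could add to it, but 4.39% of the genes called after LPS (15 of 342, exact 95% interval 2.48 to 7.13) were within 0.05 of 0 on both arrays with IL-4, an interval that spans the bound of 5% set before and does not decide. A weaker response to LPS in the presence of IL-4 stays open for single genes, not as the cause of the smaller replicate effect. Of all genes, 49.8% were that close to 0 with IL-4 and 26.9% without, and of the 191 called genes that moved at least 2-fold after LPS, 1 was that close with IL-4.

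As deposited, the cytokine list was lower with IL-4 by camera at the preset correlation but not at an estimated one (0.365), with 0 of 18 genes past the test, while the interferon-stimulated list was not called. One factor for every gene would give both lists the same slope of ratios with IL-4 on ratios without, but the slopes were 0.934 (0.828 to 1.04) for interferon-stimulated genes and 0.597 (0.376 to 0.743) for cytokines, a difference of 0.337 (0.151 to 0.568). The list medians differed by 1.01 in one replicate pair and 1.04 in the other, so the difference between these 2 lists was present in both pairs. Both tests ran on the 2 lists picked because they showed the pattern, and the bootstrap takes genes as independent. They restate the pattern that prompted them, so they do not decide on a common factor or on 1 replicate number alone. They also give no support to an effect of IL-4. Such an effect, and whether cytokines were lower or interferon-stimulated genes higher, stays open, since the medians depended on the scale. The cytokine list stayed lower after rescaling and after quantile normalization, by camera at the preset correlation only. Its median turned only when the arrays were scaled to the same spread. Interferon-stimulated genes read 0.56 after rescaling. Scaling to the same spread gave 0.31 for cytokines and 1.68 for interferon-stimulated genes. That scaling equalises the median size of all values, many of them near 0 with IL-4, and not the SD, so it does not decide the direction.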

How the results depend on the processing

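The combinations of the block with a filter or a trend, the rescaling, and the list tests under 2 array scalings were chosen after seeing the data. Counts are of genes higher and lower, from limma, and the cause of a change was not tested unless it is given. LPS against control, 161 and 181, became 0 and 0 with arrays scaled to the same spread, 59 and 54 after quantile normalization, 82 and 76 with every feature by itself, 54 and 64 with the feature of largest spread, 102 and 105 with robust moderation, and 19 and 2 with a variance trend. It became 333 and 358 without genes under 0.5 (fewer genes tested), 498 and 638 with the replicate block, 1471 and 2257 with both, 609 and 809 with trend and block, and 100 and 91 at 2-fold or more. LPS with IL-4 against control, 17 and 7, became 26 and 14 after centring, 302 and 369 when scaled to the same spread, 63 and 64 by quantiles, 1 and 0 by feature, 2 and 1 by the feature of largest spread, 3 and 2 with robust moderation, and 2 falls with the trend. It became 119 and 88 with the filter, 0 and 0 with the block, 1042 and 1377 with both, 124 and 84 with trend and block, and 86 and 67 rescaled. Both were 0 and 0 at an adjusted p under 0.01 and with only the arrays compared (fewer arrays), and 0 and 0 whichever array was left out, where 1 residual degree of freedom remained. In the fits of only the compared arrays, 2338 and 1975 genes had an unadjusted p under 0.05.

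For LPS with IL-4 against LPS, 0 and 0 in limma (1369 genes at an unadjusted p under 0.05), the filter with the block gave 342 and 336, the independent filter with the block 234 and 244, and the same rescaled 158 and 185. Each other alternative kept 0, with 297 (trend) to 2988 (without LPS replicate 2) genes at that unadjusted p. Called lists, 14, 15 and 12 in the 3 comparisons, became 0, 0 and 0 with an estimated correlation, and 13, 10 and 2 by fry. Fry kept 11 of the 14 lists after LPS, losing MHC class II (adjusted p 0.213), antimicrobial effectors (0.121) and ribosomal proteins (0.128) and adding the IL-4 and Th2 lists (0.0494 each). With IL-4 it kept 10 of 15, losing MHC class II (0.275), Th2 (0.122), monocyte and macrophage (0.0808), stress (0.0854) and ribosomal (0.269) lists. Leaving out an array gave 12 to 16, 14 to 16 and 6 to 12 lists, the last lowest without LPS replicate 1 (6) and 2 (7).

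In the difference, scaling to the same spread multiplied the arrays with IL-4 by 1.71 and the LPS arrays by 0.569 and 0.603. It turned the direction of cytokines (0.31), anti-inflammatory mediators (0.47), chemokines (2.32), interferon-stimulated genes (1.68), NF-kappaB genes (0.62), DC maturation (0.87), Th1-associated products (0.0028), MHC class II (−0.68), lysosome (−0.99) and ribosomal proteins (−0.50). Cytokines (camera adjusted p 0.882) and Th1-associated products (0.345) lost their call there and were not called in the new direction. The factors of this scaling rest on the median size of all values, and 66.6% and 64.8% of features with IL-4, against 43.6% and 46.7% without, lay within 0.05 of 0. Rescaling turned the direction of chemokines (0.14), interferon-stimulated genes (0.56) and DC maturation (0.20), with and without the block. Of these lists, only interferon-stimulated genes were called after it. With filter and block, rescaling turned Il6 (1.13) and Ccr7 (1.29). Of the 12 lists called in the difference, 6 kept direction and call when scaled to the same spread, 9 after quantile normalization and 8 after rescaling. In 55 of 3660 alternative values of named genes the sign differed with no call in either setting. The shared calls went from 19 to 0 at an adjusted p under 0.01, and r between the comparisons from 0.802 to 0.506 and 0.393 across replicate numbers. Signal over background was not used here, so its limit on weak features is unknown.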

Other observations

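Both hypotheses below, and the lists that test them, were chosen after the results were seen. The gene that prompted each was left out of its list.

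Cd36 was among the genes with the largest differences with IL-4 (3.27), though the filter kept it after rescaling only. IL-4 may therefore raise lipid uptake and PPAR target genes in these cells relative to LPS alone. Over 17 measured genes of a list of such targets, the median difference was 0.192, with 11 genes higher and 2 lower in both replicate pairs, and the camera p at the preset correlation was 0.00103 with the replicate block and 0.00108 without (0.00206 and 0.00216 adjusted over the 2 lists tested here). At an estimated correlation it was 0.210 and 0.132, so the list does not pass there and the hypothesis rests on the preset correlation. After rescaling of the arrays with IL-4 the median was 0.217 and the blocked p 0.0132. Members included Lpl (1.68), Scd2 (1.24), Abcg1 (1.16) and Pparg (0.77), which the IL-4 list also holds, whereas Abca1 read −1.70. Against control, Lpl read −2.235 with LPS and −0.56 with IL-4 added, and Scd2 −2.195 and −0.955. Abcg1 read −1.205 and −0.045, and Pparg −1.384 and −0.612. For these members the differences are smaller falls, not rises above control, while Fabp4 (0.40 and 0.592) lay above it.

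Ocstamp (2.73) is needed for the fusion of macrophages into giant cells, so IL-4 may induce a cell fusion programme. Over the 15 genes of a list for it, the median difference was −0.045, with 7 genes higher and 6 lower in both pairs, which decides nothing. Dcstamp (1.46) and Atp6v0d2 (1.43) were higher and Cd81 (−1.51) was lower.

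Among features tested by themselves in LPS against control, limma called 158, of which 11 had no single gene symbol and are in no gene value of the report.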
